A study of Mus musculus with 16 samples.

How the data were processed

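Total RNA from isolated islets was extracted with Trizol, and 150 ng was amplified and labelled with a 3′ IVT Express kit, per the labels' protocols. It was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 1 array for each of the 16 preparations. The values used are the authors' deposited log2 signals, 1 per probe set. The background correction, summarisation and normalisation behind them were not given in the sources used here. The array medians lay between 6.29 and 6.35 on the log2 scale, and no further scaling was applied. The log base was taken from the highest value, 15.39, and the medians, which are in the usual range of log2 array signals. Because arrays have an upper limit, the differences of the brightest hormone genes are compressed. Ins2, Iapp, Gcg, Ppy and Ttr lay within 0.66 of the top of the scale on average, and Sst 1.15 below it. No columns were identical, and correlations between arrays ranged from 0.971 to 0.994.

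Of 45101 probe sets, 64 Affymetrix control sets were left out. Of the rest, 34945 named 1 gene, 932 named several and 9160 named none in the platform annotation used here. Symbols were updated through gene identifiers to RefSeq on GRCm38.p6 for 34741 of them. Each of the 18193 genes was represented by its probe set with the highest mean over the 16 arrays, and 9010 genes had more than 1. Of the 942 called genes with several probe sets, 1 had another probe set called in the opposite direction. No filter on dim genes was applied and no detection calls were used, so differences against signals below the array medians are compressed by background. Genes without a probe set of their own in this annotation were not analysed here.

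Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with genotype as the only term. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The 23 gene lists, with 545 entries of which 490 were measured, were written from general knowledge before the data were examined, as were the main test, most of the alternatives and the rule for naming genes. Some genes are on more than 1 list. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation. After the data were seen, the mean of each list per array was also tested by an exact permutation of the group labels, over all splits and within pairs, with Benjamini-Hochberg adjustment over the 23 lists. The share of called genes within 20 Mb of Insm1 was compared with that of all other placed genes by Fisher's exact test, with gene positions used only to find neighbours.

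The genes named are Insm1, the 12 largest rises and 12 largest falls among called genes, up to 4 called members of each list (or the member with the lowest p), a fixed set of islet genes, and up to 6 called genes near Insm1. This gave 96 genes, of which 78 were called.

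Replicate numbers are shared by the groups in the labels. Deviations from the group means correlated between arrays of the same number in all 8 pairs (0.237 to 0.735, median 0.466), against a median of −0.10 between other numbers, and 13 of 16 arrays correlated best with their own number. The numbers were therefore taken to pair the arrays, and the fit with the replicate block is given where it changed the call of a named gene or list, or a count of called genes. That same-numbered animals were littermates is not stated in the labels.

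The alternatives were quantile normalisation, median centring, leaving out dim genes, averaging probe sets, no variance trend, array weights, the replicate block, a Y-linked or acinar marker mean as a covariate, leaving out each array, testing every probe set, an estimated correlation in camera and a 10 Mb window. Chosen after seeing the data were an immune marker covariate, leaving out pairs 1 to 3, the block with 1 or both marker covariates, the mean 3′ minus 5′ difference of the Gapdh and beta-actin control probe sets as a covariate with and without the block, the block with an estimated correlation, and the exact tests of list means. A change of sign with no call on either side was not counted as a reversal.

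The steps were tested on simulated data for this comparison, drawn from independent normal distributions with the means and SDs of the 18193 genes. Of 100 genes changed 1.5-fold, 85 were recovered, and of 100 changed 3-fold, 100. Of all genes called there, 5% had not been changed. The simulated arrays had no pairs and no correlation between genes, so they do not test the lists' calibration. RNA quality was checked on the control probe sets. The 3′ minus 5′ difference of Gapdh was lower in the mutant by 0.07 in 8 of 8 pairs (exact paired permutation p = 0.00781, adjusted p = 0.039), and that of beta-actin by 0.09 in 7 of 8 (exact paired permutation p = 0.0156, adjusted p = 0.052). Over all splits neither passed (exact permutation, adjusted p = 0.184 for both). Figures were drawn with matplotlib 3.10.9.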

Results

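Gene expression was measured in pancreatic islets from mice in which Insm1, a zinc finger transcription factor of endocrine cells, had been deleted in adult beta cells. There were 16 arrays, 1 per islet preparation, from 8 mutant and 8 control animals. All animals carried RIPcreER, a tamoxifen-inducible recombinase under the rat insulin promoter. The mutants had 1 floxed and 1 lacZ allele of Insm1, and the controls had 1 floxed and 1 wild-type allele. Only the mutants thus carried the lacZ allele, in beta cells and in other cells alike. Each animal received a 25 mg tamoxifen pellet with 21-day release at 4 to 5 weeks of age, and islets were taken at 8 to 12 weeks. The mice were of mixed C57BL/6, 129/ola and CBA/J background, and the series text describes the controls as litter-matched. Since both groups had the recombinase and tamoxifen, the floxed allele could also be deleted in control beta cells, which kept 1 wild-type allele. The comparison of the groups thus asks which islet transcripts differ when that wild-type allele is replaced by the lacZ allele. It is not a comparison with intact Insm1. Values are log2 signals of probe sets, 18193 genes were tested, and differences are mutant minus control with n = 8 per group throughout. The number of arrays limits the precision of each value.

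Insm1 itself did not differ past the threshold. The brighter of its 2 probe sets read 11.26 ± 0.23 (SD, n = 8) in controls and 11.02 ± 0.22 in mutants, a difference of −0.25 ± 0.11 (SE, adjusted p = 0.182 over genes). It was lower in the mutant in 5 of 8 pairs. The other probe set read 10.54 ± 0.16 and 10.49 ± 0.15, a difference of −0.05 ± 0.08 (adjusted p = 0.79 over probe sets). The difference of the brighter probe set was 0.04 without pairs 1 to 3 (adjusted p = 0.873). With the replicate block it was −0.57 with the acinar mean as a covariate, 0.25 with the acinar and immune-cell means, and 0.03 with the 3′ minus 5′ signal of control transcripts (adjusted p = 0.269, 0.842 and 0.982), so its direction was not settled. The position of these probes relative to the deleted part of the gene was not given in the sources used here, so the signal of Insm1 does not check the genotype labels.

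Expression of 1594 genes differed between mutant and control islets, 746 of them higher in the mutant and 848 lower. The median size of their changes was 0.41 on the log2 scale, and 434 changed at least 1.5-fold, 231 up and 203 down. At least 2-fold changes were called for 153 genes, 85 up and 68 down. The mutant array differed from its same-numbered control in 1 direction in all 8 pairs for 1309 of the 1594 genes. With the 8 replicate numbers as pairs in the fit, 3200 genes were called, 1433 up and 1767 down, and 1582 of the 1594 were among them in the same direction. Without pairs 1 to 3, in which mutant arrays had high immune-cell marker signal, 828 genes were called, and the changes of the 1594 kept their direction, with a median ratio of 0.987 to those from all arrays. The 19 named genes that lost their call there kept a median of 0.851 of their change (0.598 to 1.14).

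The largest measured rises were those of C4bp, which encodes a complement-binding protein, and ccdc198. C4bp went from 4.34 ± 0.09 (SD) in controls to 9.19 ± 0.23 in mutants, a difference of 4.84 ± 0.09 (SE, adjusted p = 1.67e-16). ccdc198 went from 5.27 ± 0.45 to 9.89 ± 0.87 (adjusted p = 5.68e-08). Aldh1a3, a retinaldehyde dehydrogenase seen in dedifferentiated beta cells, rose 13.1-fold, from 6.50 ± 0.93 to 10.22 ± 1.24 (adjusted p = 0.000114). Serpina1b rose 10.6-fold, although its probe set carries the suffix that marks possible cross-hybridisation among related genes. The probe sets used for Muc4, Ins2 and Map1lc3a, named below, carry the same suffix. Plet1 and Crmp1 rose 7.12-fold and 7.10-fold. The other 6 of the 12 largest rises were Edil3, Klhl29, Pdzrn3, Slc26a3, Reep1 and Bmp2, a bone morphogenetic protein, by 2.52 to 2.11 on the log2 scale. All 12 were higher in the mutant in 8 of 8 pairs. For 7 of the 12 (C4bp, ccdc198, Klhl29, Pdzrn3, Slc26a3, Reep1 and Bmp2) the control mean lay below the lowest array median of 6.29. No detection calls were used here, so such differences are differences of signal, which background compresses, and the order by size is that of signals.

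The largest fall was that of Trpm5, a calcium-activated cation channel, which dropped by 2.75 ± 0.27 (SE) on the log2 scale, from 10.40 ± 0.58 (SD) to 7.65 ± 0.60 (adjusted p = 4.95e-06). Lyve1, a hyaluronan receptor, was lower by −2.56 ± 0.33, and Muc4, a membrane mucin, was 4.34-fold lower. Of the 3 Muc4 probe sets 2 were called lower, and 1 was higher but not called. Ica1l, Cox6a2, Tex15, Plut, Th, Adora3, Prss53, Kdm2b and Gm17767 completed the 12 largest falls, between −1.97 and −1.60 on the log2 scale. The mutant means of Lyve1, Ica1l and Tex15 (5.80, 4.78 and 4.99) lay below 6.29, so the same limit holds for these 3. Plut is a long noncoding RNA gene that overlaps Pdx1 in the RefSeq annotation of GRCm38.p6, and Th encodes tyrosine hydroxylase. All 12 were lower in the mutant in 8 of 8 pairs. The call of Gm17767 (adjusted p = 0.0293) was lost when any 1 of 7 arrays was left out (mutant replicates 2, 4, 5 and 7, control replicates 3, 6 and 8), with adjusted p up to 0.0618, and without pairs 1 to 3, where its difference was as large (−1.66 against −1.60, adjusted p = 0.217).

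**Figure D1:**
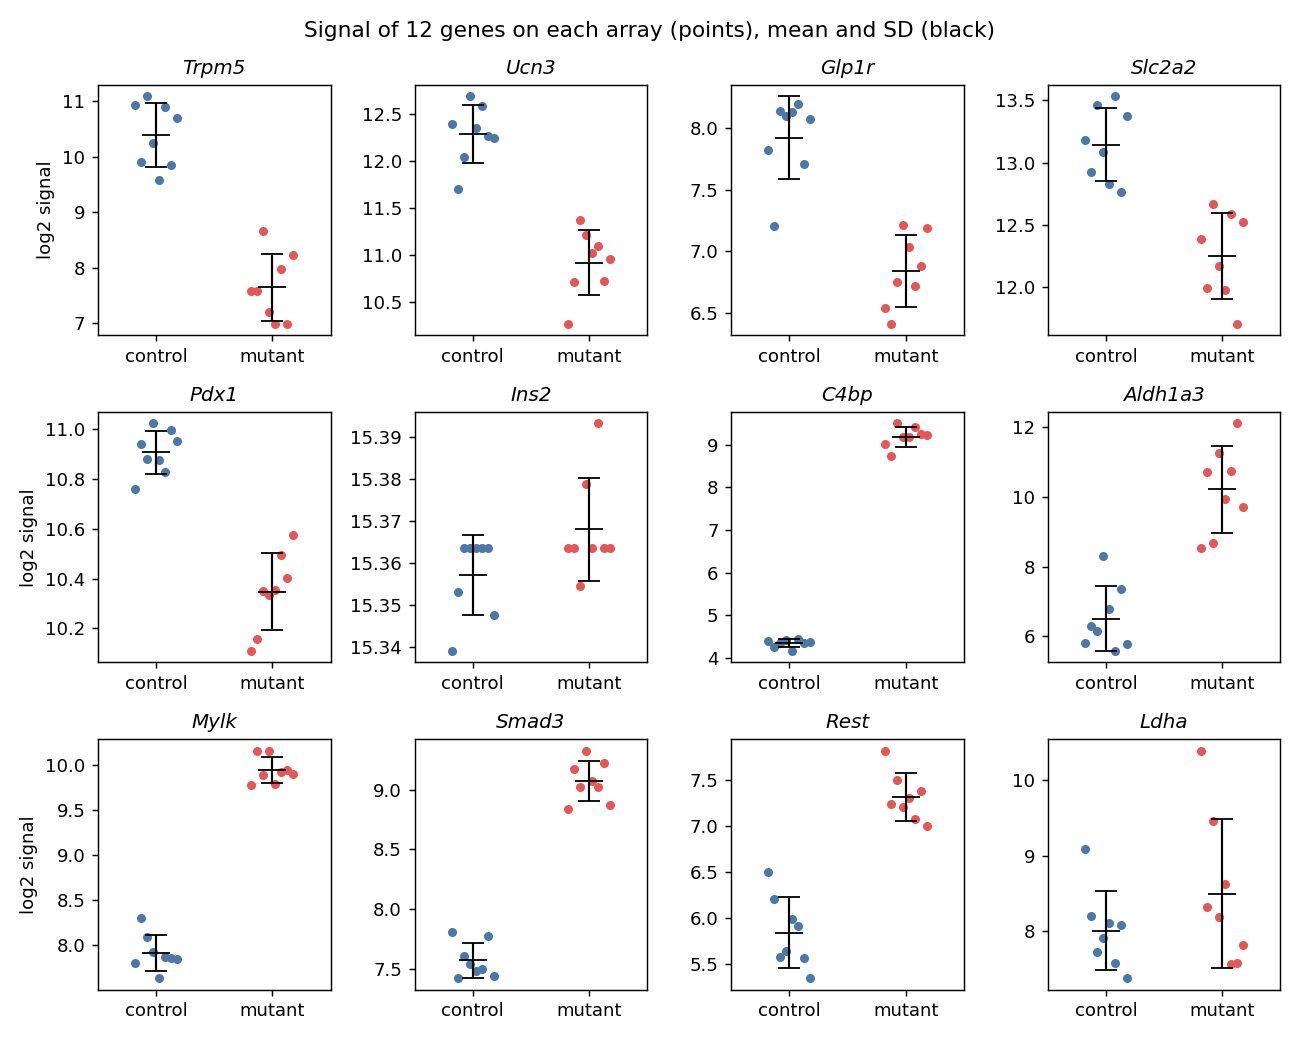
Log2 signal (vertical axes) of 12 genes on each control (blue) and mutant (red) array, with the mean and SD of 8 arrays in black. The groups do not overlap for Trpm5, Ucn3, Slc2a2, Pdx1, C4bp, Aldh1a3, Mylk, Smad3 and Rest, those of Glp1r touch, Ins2 lies between 15.34 and 15.39 on all 16 arrays, and Ldha overlaps.

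Genes of mature beta cells fell. Of the 21 measured members of the list, 13 fell and 2 rose (14 and 2 when adjusted over the list alone), and the median change was −0.39. Ucn3, a peptide hormone of mature beta cells, was 2.58-fold lower (−1.37 ± 0.15, adjusted p = 1.79e-05). The GLP-1 receptor gene Glp1r was 2.11-fold lower (−1.08 ± 0.15, adjusted p = 0.000125). Slc2a2, the beta-cell glucose transporter, was 1.86-fold lower (−0.89 ± 0.15, adjusted p = 0.000827). The KATP channel subunit gene Abcc8 moved the other way, by 0.22 ± 0.06 (adjusted p = 0.0404), a call that was lost when any 1 of 10 arrays was left out (mutant replicates 2, 4, 6, 7 and 8, control replicates 1, 3, 4, 5 and 6; adjusted p up to 0.0814). It was also lost with quantile normalisation, median centring, the acinar mean as a covariate and without pairs 1 to 3 (adjusted p = 0.0651, 0.0617, 0.129 and 0.0995). Ins2 read 15.36 ± 0.01 in controls and 15.37 ± 0.01 in mutants, 0.03 below the highest value of the data on average, so this probe set cannot show a change in insulin transcript. By limma's camera the list was lower than other genes (adjusted p = 2.8e-09), also with an estimated correlation (adjusted p = 0.0185), but not with that correlation and the replicate block together (adjusted p = 0.0561). The mean of the list per array was lower in the mutant by 0.49 and in 8 of 8 pairs (exact permutation test, adjusted p = 0.000891).

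Of 26 measured stimulus-secretion coupling genes, 7 of which are also on the list of mature beta-cell genes, 10 fell and 2 rose (11 and 3 over the list alone, 12 and 3 with the replicate block). The camera test called the list lower (adjusted p = 0.000356), but not with an estimated correlation (adjusted p = 0.181, and 0.197 with the replicate block). Besides Trpm5, Glp1r and Slc2a2, the calcium channel subunit gene Cacna2d1 was lower by −0.43 ± 0.06 (adjusted p = 0.000229) and the SERCA2 calcium pump gene Atp2a2 by −0.42 ± 0.07 (adjusted p = 0.000536). All 6 called probe sets of Atp2a2 fell, whereas the fall of Cacna2d1 was no longer called with the mean of its probe sets (−0.23, adjusted p = 0.282). The list mean was lower in 8 of 8 pairs (−0.30, exact permutation test, adjusted p = 0.000891), while the median change was −0.18. Shared members, above all Trpm5 (−2.75), weigh on this mean, although Abcc8, also shared, rose. The list without its shared members was not tested, so it is no independent result beside the mature beta-cell list.

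Islet transcription factors changed in part. Of 23 measured, 5 fell and 1 rose (6 and 1 over the list alone). Pdx1, a regulator of beta-cell identity, was lower by −0.56 ± 0.07 (adjusted p = 2.9e-05), Nkx6-1 by −0.39 ± 0.08 (adjusted p = 0.00302) and Mnx1 by −0.68 ± 0.15 (adjusted p = 0.00873). Hnf4a rose by 0.35 ± 0.06 (adjusted p = 0.000688). The differences for Neurod1 (−0.16 ± 0.10), Foxa2 (−0.02 ± 0.08), Nkx2-2 (−0.07 ± 0.06) and Pax6 (−0.16 ± 0.06) did not pass the test, with adjusted p = 0.403, 0.943, 0.534 and 0.123. The call of Nkx6-1 was lost without pairs 1 to 3 (adjusted p = 0.0764). The list was called by camera (adjusted p = 0.0184) and by the exact permutation test of its mean (−0.13, adjusted p = 0.0149, lower in 7 of 8 pairs). It was not called with an estimated correlation (adjusted p = 0.472) nor by the exact permutation test within pairs (adjusted p = 0.0797). Its camera call was also lost without dim genes, with the Y-linked or immune-cell mean as a covariate, without pairs 1 to 3 and without mutant replicate 3 (adjusted p = 0.0712, 0.0769, 0.104, 0.324 and 0.0685). With the replicate block it was lost with the acinar and immune-cell means or the 3′ minus 5′ signal as covariates (adjusted p = 0.0758 and 0.0617).

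For the secretory granule and exocytosis list, 6 of 36 members fell and 1 rose (6 and 4 over the list alone, 8 and 5 with the replicate block). The exocytosis gene Sytl4 was 1.53-fold lower (adjusted p = 0.000134), and the zinc transporter gene Slc30a8 1.26-fold lower (adjusted p = 0.000764). Pclo was 1.23-fold lower (adjusted p = 0.0022), a call lost without pairs 1 to 3 (adjusted p = 0.0771). Pcsk1, a prohormone convertase gene, differed by −0.17 ± 0.16 (adjusted p = 0.61). The list itself was not called (adjusted p = 0.15), and was called lower with the acinar mean as a covariate (adjusted p = 0.00417, and 9.75e-05 with the replicate block as well). With an estimated correlation its adjusted p was 0.758.

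Of 28 measured genes that are normally kept low in beta cells, often called disallowed genes, 7 rose and 0 fell (10 and 0 over the list alone, 12 and 0 with the replicate block), with a median change of 0.28. The camera test called the list (adjusted p = 4.66e-08), but not with an estimated correlation (adjusted p = 0.0928, and 0.207 with the replicate block). Mylk, encoding myosin light chain kinase, was 4.07-fold higher (adjusted p = 1.44e-10), and Smad3, a TGF-beta signal transducer, 2.82-fold higher (adjusted p = 1.87e-09). The Hippo pathway effector gene Yap1 was 1.62-fold higher (adjusted p = 5.28e-05) and the low-Km hexokinase gene Hk1 1.63-fold higher (adjusted p = 0.00321). Ldha, lactate dehydrogenase A, differed by 0.49 ± 0.36 (adjusted p = 0.491), and was called higher with the acinar mean as a covariate (1.10, adjusted p = 0.0138). Its highest signals were on mutant replicates 1 and 3 and control replicate 1 (10.39, 9.45 and 9.09). These arrays also had the highest immune-cell marker means (9.44, 9.14 and 8.47), so its signal may follow other cells in the preparation. The call of the list was also lost with the replicate block and the 3′ minus 5′ signal, where the median change was 0.07 (adjusted p = 0.147), and with the block and the acinar and immune-cell means, where it was 0.08 (adjusted p = 0.0758). Its mean was higher in 8 of 8 pairs (0.40, exact permutation test, adjusted p = 0.0057).

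Genes of immature and progenitor endocrine cells rose as a list. Of 24 measured, 6 rose and 1 fell (8 and 1 over the list alone, 9 and 1 with the replicate block), and 17 were not called. The median change was 0.19, with 16 differences above 0 and 8 below. Besides Aldh1a3, these included Rest, a repressor of neuronal genes, by 1.48 ± 0.15 (adjusted p = 8.18e-06, from a control mean of 5.84, below the array medians), the tetraspanin gene Cd81 at 1.86-fold (adjusted p = 7.62e-05), and Amotl2 at 1.42-fold (adjusted p = 0.000262). Npy differed by 0.62 ± 0.42 (adjusted p = 0.448). The list was called by camera (adjusted p = 0.000279) and with an estimated correlation (adjusted p = 0.0127), though not with that correlation and the replicate block (adjusted p = 0.0632). Its mean was higher in 8 of 8 pairs (0.41, exact permutation test, adjusted p = 0.000891). Aldh1a3, with a difference of 3.72, and Rest weigh on this mean, which lay above the median, and the list without them was not tested.

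Alpha-cell markers rose as a list. Of 14 measured, 5 rose and 0 fell (9 and 0 over the list alone and also with the replicate block). Dpp10 was 2.78-fold higher (adjusted p = 4.7e-07), and the transcription factor genes Irx2 and Irx1 were 1.68-fold and 1.46-fold higher (adjusted p = 0.00791 and 0.00972). Nrip1 was 1.23-fold higher (adjusted p = 0.0131), a call lost without pairs 1 to 3 (adjusted p = 0.0999). Glucagon, Gcg, differed by 0.07 ± 0.05 (adjusted p = 0.465), but lies 0.36 below the top of the scale. The list was called by camera (adjusted p = 8.87e-07) and with an estimated correlation (adjusted p = 0.0185), but not with that correlation and the replicate block (adjusted p = 0.118). Its mean was higher in 8 of 8 pairs (0.39, exact permutation test, adjusted p = 0.000891).

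Of 13 measured delta-cell and PP-cell markers, 2 rose and 0 fell (4 and 0 over the list alone, 4 and 1 with the replicate block). Cd24a was 1.84-fold higher (adjusted p = 4.03e-05) and Rbp4 1.41-fold higher (adjusted p = 0.0213, but 0.0612 with the acinar mean as a covariate and 0.0798 without pairs 1 to 3). Sst differed by 0.15 ± 0.07 (adjusted p = 0.247). Ppy differed by 0.21 ± 0.07 (adjusted p = 0.0971, and 0.0372 with the replicate block). The list was not called (adjusted p = 0.0596), and was called with the replicate block (adjusted p = 0.0432), with median centring, array weights or the immune-cell mean, without dim genes, and without mutant replicate 1, 3 or 7 or control replicate 5 or 7 (adjusted p from 0.0168 to 0.0499). With an estimated correlation it was not called (adjusted p = 0.472, and 0.483 with the replicate block).

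**Figure D2:**
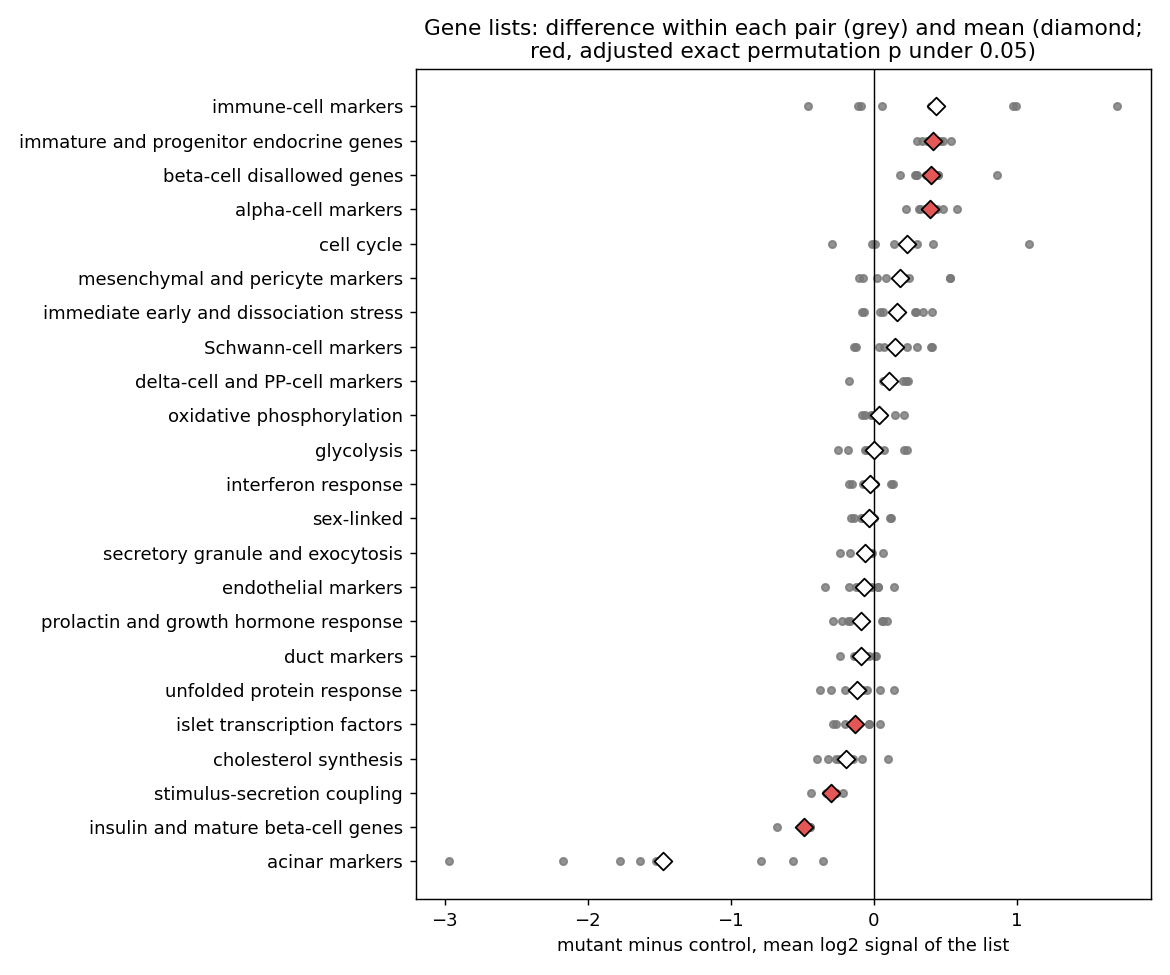
Difference between mutant and control in the mean log2 signal of each of 23 gene lists (horizontal axis), for the 8 pairs (grey) and on average (diamonds, red where the adjusted p of the exact permutation test over all splits is under 0.05). Mature beta-cell genes, stimulus-secretion coupling and islet transcription factors lie below 0, and disallowed, immature and alpha-cell genes above 0, all in red.

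Markers of acinar cells, which make digestive enzymes and can be carried along with islets, were lower in mutant preparations. Their mean per array was 11.48 ± 1.09 (SD) in controls and 10.01 ± 1.71 in mutants, and lower in 8 of 8 pairs. The exact permutation test gave an adjusted p of 0.177 over all splits and 0.0299 within pairs. Of 27 measured markers 0 were called (0 over the list alone), and 22 were called lower with the replicate block. The marker with the lowest p, Rnase1, differed by −1.94 ± 0.69 (adjusted p = 0.0949, and 0.00335 with the replicate block). It was also called without mutant replicate 1, without pairs 1 to 3, with array weights and with the immune-cell mean as a covariate (adjusted p = 0.027, 0.0205, 0.0432 and 0.00489). The camera test called the list (adjusted p = 8.87e-07), but not with an estimated correlation (adjusted p = 0.559). The lower acinar signal of the mutants thus went along with the differences of the beta-cell, disallowed, immature and alpha-cell lists in the same 8 pairs.

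A sign of RNA quality moved with the genotype in the same pairs. The 3′ minus 5′ signal of the Gapdh control probe sets was −0.19 ± 0.10 (SD) in controls and −0.26 ± 0.07 in mutants, lower in 8 of 8 pairs, and that of beta-actin was 1.07 ± 0.13 and 0.97 ± 0.08, lower in 7 of 8. By exact permutation within pairs the adjusted p was 0.039 and 0.052, and over all splits it was 0.184 for both. This difference thus also went along with those of the beta-cell, disallowed, immature and alpha-cell lists. With the mean of both differences as a covariate, 1064 genes were called, 949 of them among the 1594 in the same direction. All 1594 changes kept their sign, with quartiles of 0.855 and 1.08 for their ratio to the original ones. In the fit with the replicate block as well, 238 genes were called, 215 of them among the 1594. Of the 78 called named genes, 45 lost their call in the fit with the block and this covariate, 39 with the block and the acinar mean, and 74 with the block and the acinar and immune-cell means. The changes of these genes had a median ratio to the original ones of 0.899, 0.853 and 0.881, while their median SE rose from 0.12 to 0.189, from 0.125 to 0.178 and from 0.139 to 0.283. Aldh1a3, for example, differed by 3.72 in the last fit and in the original one. With the covariate alone, 15 named genes lost their call (adjusted p from 0.0636 to 0.2), namely Gm17767, Irx1, Irx2, Nrip1, Rbp4, Acta2, Col6a1, Asns, Trib3, Pfkp, Cox4i1, Atp5c1, Ifit1, Egr2 and Nr4a2. Their changes were a median of 0.746 times the original ones, from 0.544 for Pfkp to 1.16 for Col6a1. Pecam1 and Msmo1 gained one (adjusted p = 0.0491 and 0.0293), and the unfolded protein response list lost its call (adjusted p = 0.307).

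The mean of immune-cell markers was 9.44, 8.20 and 9.14 in mutant replicates 1 to 3 and 8.47 in control replicate 1, and between 7.21 and 7.76 on the other 12 arrays. Over the groups it was 7.55 ± 0.41 (SD) in controls and 7.99 ± 0.86 in mutants (exact permutation test, adjusted p = 0.348). Of 26 measured markers 1 was called (1 over the list alone). This was C1qa, a macrophage complement gene, which was higher by 0.88 ± 0.19 and in 8 of 8 pairs (adjusted p = 0.00598). Without pairs 1 to 3 its difference was 0.82, no longer called with fewer arrays (adjusted p = 0.114). The camera call of the list (adjusted p = 0.000489) was lost with an estimated correlation (adjusted p = 0.59) and without pairs 1 to 3, where the median change was −0.0091 (adjusted p = 0.74). It was also lost with the replicate block and the 3′ minus 5′ signal (adjusted p = 0.8).

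**Figure D3:**
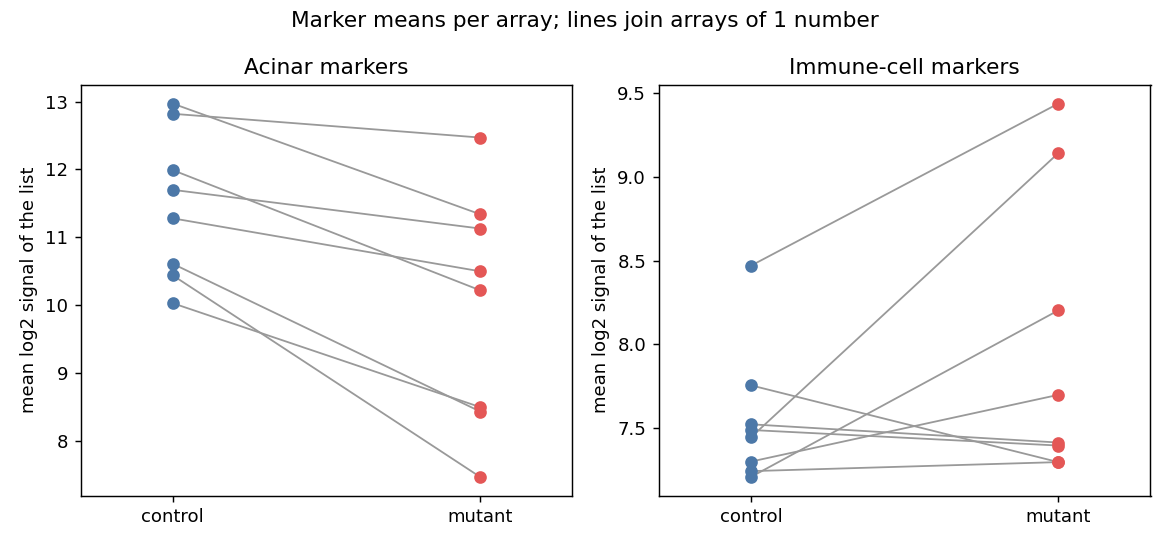
Mean log2 signal (vertical axes) of 27 acinar markers (left) and 26 immune-cell markers (right) on control (blue) and mutant (red) arrays, with lines joining arrays of the same replicate number. The acinar mean was lower in the mutant in all 8 pairs, and the immune mean was above 8 on 3 mutant arrays and 1 control array.

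Among the markers of other cells, 3 of 20 mesenchymal genes rose and 1 fell (4 and 2 over the list alone, 5 and 3 with the replicate block). The rise of Col6a1 (adjusted p = 0.0475) lost its call when any 1 of 11 arrays was left out (adjusted p up to 0.095). It also did with quantile normalisation and with the Y-linked or immune-cell mean (adjusted p = 0.0574, 0.111 and 0.0965). The proteoglycan gene Dcn was 2.44-fold higher and the collagen gene Col1a2 1.52-fold higher, whereas smooth muscle actin, Acta2, was 1.98-fold lower (adjusted p = 0.00814, 0.0145 and 0.0105). Dcn and Col1a2 turned direction and lost their calls with the replicate block and the 3′ minus 5′ signal (−0.0297 and −0.0438, adjusted p = 0.984 and 0.97). The list was called by camera (adjusted p = 0.0329), but not with the replicate block (adjusted p = 0.0667) or an estimated correlation (adjusted p = 0.59). Its call was also lost without dim genes, with the Y-linked or immune-cell mean, without pairs 1 to 3, and without mutant replicate 2, 3 or 8 or control replicate 8 (adjusted p from 0.0507 to 0.298). With the replicate block it was lost with the acinar mean (adjusted p = 0.744), and its median turned to −0.10 with the acinar and immune-cell means and −0.15 with the 3′ minus 5′ signal (adjusted p = 0.333 and 0.0782). Of 14 duct markers 1 rose and 1 fell (1 and 1 over the list alone, 2 and 2 with the replicate block). Tspan8 was 1.80-fold higher (adjusted p = 4e-04), and the keratin gene Krt19 was 1.93-fold lower (adjusted p = 0.0113, and 0.06 without pairs 1 to 3). The duct list was not called (adjusted p = 0.305). Of 21 endothelial and 9 Schwann-cell markers 0 were called, with 0 over each list alone (1 endothelial marker was lower with the replicate block), and the lowest p belonged to Pecam1 (0.18 ± 0.07, adjusted p = 0.126) and Erbb3 (0.18 ± 0.11, adjusted p = 0.355). Neither list was called (adjusted p = 0.351 and 0.148), but the endothelial list was called lower with the replicate block and the acinar mean (−0.11, adjusted p = 0.00989). With an estimated correlation the endothelial list was not called (adjusted p = 0.758, and 0.739 with the replicate block). Of the 4 sex-linked genes 0 were called (0 over the list alone). The lowest p was that of Uty (−0.12 ± 0.09, adjusted p = 0.547), and the list was not called (adjusted p = 0.757).

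Of 29 unfolded protein response genes 3 fell and 0 rose (3 and 0 over the list alone), and with the replicate block 10 fell and 1 rose. The fall of Trib3 (adjusted p = 0.0347) lost its call when any 1 of 11 arrays was left out (adjusted p up to 0.0712). The amino acid enzyme gene Asns was 1.48-fold lower (adjusted p = 0.00912, and 0.207 without pairs 1 to 3), and Edem1 1.31-fold lower (adjusted p = 0.00605, and 0.14 with the mean of its probe sets). The camera call of that list (adjusted p = 0.0489) was lost with an estimated correlation (adjusted p = 0.652), and without any 1 of 9 arrays (mutant replicates 1, 2, 3, 6 and 7, control replicates 2, 3, 5 and 8; adjusted p up to 0.119). It was also lost without dim genes, without the variance trend, with array weights, with the immune-cell mean and without pairs 1 to 3 (adjusted p = 0.114, 0.0511, 0.0963, 0.27 and 0.753). With the replicate block it was lost with the acinar and immune-cell means (adjusted p = 0.776), and with the 3′ minus 5′ signal, where the median was 0.04 (adjusted p = 0.402). Of 22 interferon response genes 4 fell and 0 rose (4 and 1 over the list alone, 4 and 2 with the replicate block). These included, with Oasl2 and Oas2 below the array medians in both groups, Oasl2, Oas1a and Oas2 of the oligoadenylate synthetase family, by −0.44, −0.50 and −0.31 (adjusted p = 0.00147, 0.00217 and 0.00692). The call of Oas2 was lost without pairs 1 to 3 (adjusted p = 0.103), and the list was not called (adjusted p = 0.399), except as lower with the immune-cell mean as a covariate (adjusted p = 0.0167). With an estimated correlation its adjusted p was 0.758. Its median change was above 0 (0.0018) and its mean below (−0.03). Of 17 cholesterol synthesis genes 0 were called (0 over the list alone), and 5 fell with the replicate block. Msmo1 had the lowest p (−0.70 ± 0.22, adjusted p = 0.0626, and 0.00111 with the replicate block). It was also called without dim genes, with the mean of probe sets, and without mutant replicate 4, 5 or 7 (adjusted p = 0.0441, 0.0138, 0.0379, 0.0438 and 0.0209). The camera call of that list (adjusted p = 0.0329) was lost with an estimated correlation (adjusted p = 0.652), and without mutant replicate 2, 3, 6 or 8 or control replicate 4 or 5 (adjusted p up to 0.198). It was also lost without dim genes, with the Y-linked or immune-cell mean and without pairs 1 to 3 (adjusted p = 0.0712, 0.142, 0.182 and 0.0959). With the replicate block it was lost with the acinar mean and with the 3′ minus 5′ signal (adjusted p = 0.672 and 0.16), and with the acinar and immune-cell means the list was called higher (0.14, adjusted p = 0.034).

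Of 17 glycolysis genes 2 rose (2 over the list alone, and 2 up and 2 down with the replicate block), among them Hk1, and the list was not called (adjusted p = 0.818), with a median change of −0.06 and a mean of 0.0013. Of 31 oxidative phosphorylation genes 2 rose (2 over the list alone, and 2 up and 1 down with the replicate block), Cox4i1 by 0.18 ± 0.05 and Atp5c1 by 0.16 ± 0.04 (adjusted p = 0.0176 and 0.0217). Both calls were lost without pairs 1 to 3 (adjusted p = 0.154 and 0.158) and with the acinar mean as a covariate (0.0548 and 0.0702), and that of Atp5c1 also with median centring and the mean of its probe sets (0.0505 and 0.306). The named genes that lost their call with the acinar mean alone, these 2 among them, kept 0.753 to 0.892 of their change. The list was not called (adjusted p = 0.108), except with the immune-cell mean (0.0133), with the replicate block and the acinar mean (0.0165) and without mutant replicate 1 or control replicate 4, 6 or 8 (0.0302 to 0.0339). With an estimated correlation its adjusted p was 0.758. Of 25 immediate early genes 2 rose (2 over the list alone, and 5 up and 1 down with the replicate block), Egr2 by 1.03 ± 0.28 from a control mean of 6.14, below the array medians, and Nr4a2 2.11-fold (adjusted p = 0.025 and 0.0253). The call of Egr2 was lost without control replicate 7 or 8 and without pairs 1 to 3 (adjusted p = 0.0511, 0.0531 and 0.0561). That of Nr4a2 was lost without mutant replicate 5 or control replicate 6, 7 or 8 and with the immune-cell mean (adjusted p from 0.0504 to 0.0565). The list was not called (adjusted p = 0.0599), but was with the replicate block (adjusted p = 0.0087, and 0.023 with the 3′ minus 5′ signal as well), with median centring, the mean of probe sets, array weights or the acinar mean, without pairs 1 to 3, and without any 1 of 7 arrays (mutant replicates 6 to 8, control replicates 1, 2, 4 and 5), with adjusted p up to 0.0497. With an estimated correlation it was not called (adjusted p = 0.758, and 0.554 with the replicate block). Of 30 cell cycle genes 0 were called (0 over the list alone), and 3 rose with the replicate block. Mcm7 had the lowest p (0.58 ± 0.30, adjusted p = 0.282, and 0.00131 with the replicate block). The cell cycle list had an adjusted p of 0.0829, and of 0.00118 with the replicate block. It was also called with median centring (0.0464), with the acinar mean (5.92e-05), and without mutant replicate 4, 5 or 7 or control replicate 1 or 3 (0.00851 to 0.0196). Calls also came with the replicate block together with the acinar mean, with the acinar and immune-cell means and with the 3′ minus 5′ signal (1.14e-11, 7.38e-06 and 1.32e-08). With an estimated correlation it was not called (adjusted p = 0.758, and 0.554 with the replicate block).

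In the prolactin and growth hormone response list 3 of 13 genes fell and 1 rose (6 and 1 over the list alone, 5 and 1 with the replicate block). Tph2, a tryptophan hydroxylase of serotonin synthesis, was higher by 2.10 ± 0.13 (adjusted p = 9.7e-09), from a control mean of 4.49, below the array medians. Matn2 was 2.23-fold lower (adjusted p = 4.59e-05) and Socs2 1.36-fold lower (adjusted p = 0.0233, and 0.0553 without pairs 1 to 3). The fall of Ccnd1 (adjusted p = 0.0364) lost its call when any 1 of 11 arrays was left out (adjusted p up to 0.0753). The list was not called (adjusted p = 0.175, median −0.13), but was called lower with the replicate block and the 3′ minus 5′ signal (median −0.25, adjusted p = 0.0304). With an estimated correlation it was not called (adjusted p = 0.472, and 0.487 with the replicate block). In all, camera called 11 of the 23 lists, and splits of the 16 arrays at random called a median of 7. Only 1 of the other splits called 0 lists. Camera calls at the preset correlation, and their number, therefore carry less weight than the exact permutation tests of single lists, which called 6.

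Genes close to Insm1 were not called more often than others. Within 20 Mb of Insm1 on chromosome 2, 29 of 426 genes were called (6.81%), against 1559 of 17605 placed elsewhere (8.86%). The odds ratio was 0.75, with a 95% interval of 0.495 to 1.10 (Fisher's exact test, two-sided, p = 0.165). The called genes in this window with the lowest p included Bmp2 (higher by 2.11), Sirpa (1.66-fold lower), Sdc4 (2.16-fold higher), Map1lc3a (higher by 0.38 on the log2 scale) and Srsf6 (1.31-fold higher), besides Hnf4a.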

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

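The tests of lymphoid tissue, of acinar tissue within pairs, of RNA quality, of the share of beta cells and of acinar tissue for the beta-cell genes were chosen after the result was seen, as were the counts of splits for genes at 1.5-fold and for genes among splits that part every pair.

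1 array stood far from the rest of its group of 8 in 6 of 192 tests of genes and 4 of 46 tests of list means, and chance gives about 1 in 20. Among genes, Crmp1 read 8.78 in control replicate 8 against 7.90 to 8.19 on the other controls. Ifit1 read 6.05 there, against 6.57 to 7.02. Lyve1 read 7.26 in mutant replicate 2 (others 5.24 to 5.85) and Tex15 read 6.21 in mutant replicate 3 (others 4.49 to 5.13). Adora3 read 7.92 in control replicate 7 (others 9.06 to 9.65) and Gcg 14.76 in control replicate 2 (others 14.94 to 15.08). Among list means, mutant replicate 1 was low for granule genes (10.49, others 10.71 to 10.86) and for endothelial markers (7.69, others 8.05 to 8.29). The alpha-cell mean was 10.26 in mutant replicate 6 (others 9.82 to 10.02), and the immune-cell mean was 8.47 in control replicate 1 (others 7.21 to 7.76). Of the 10092 probe sets with no gene or several genes, which the comparisons did not use, 316 were higher in the mutant and 129 lower.

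The difference between the genotypes was set against other splits of the arrays. Of 100 splits into 8 and 8, 1, the real one, called as many as 1594 genes, and the highest other called 593, with mutants 1, 2, 3, 5, 6, 7 and 8 and control 1 on a side, thus close to the real split. At 1.5-fold, 1 of 100 reached the real 434, and the highest other called 142. Among 100 of the 128 splits that part every pair, 1 reached 1594, and the highest other called 9. This argues against chance for both counts, although 100 splits cannot show a share below 1 in 100. For the number of lists called by camera, chance stays open. Of 100 splits, 17 called as many as the real 11, with 15 in the highest other, and of the 100 that part every pair 12 did, with 18.

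Carry-over of other tissue, RNA quality or a difference in sex could give gene calls of their own. With the acinar mean as a covariate, 1337 of the 1594 called genes were called in the same direction. With the immune-cell mean 1327 were, and with the 3′ minus 5′ signal of control transcripts 949. This argues against each of these 3 as the whole source. With the Y-linked mean 1350 were, but that covariate held little contrast of sex, so its test does not count. The Y-linked mean was 8.44 to 8.70 on all 16 arrays. Xist, a transcript of female cells, read 5.07 to 5.46, below the array medians. These values argue against a difference in sex between the groups. Within pairs the acinar mean and the Gapdh 3′ minus 5′ signal were always lower in the mutant, and with pairs in the fit only 310 of the 1594 remained called with the acinar mean and 215 with the 3′ minus 5′ signal. The log2 changes of the 1594 had a median ratio to the original ones of 0.992 (quartiles 0.772 and 1.19) and 1 (quartiles 0.759 and 1.24), with a median size of 0.399 and 0.403 against 0.41, while the median SE rose from 0.0878 to 0.135 and 0.145, so by the medians calls ended through a wider error, and a part in single genes stays open. With pairs and both the acinar and immune-cell means in the fit, 9 of the 1594 remained called and 1509 kept their sign. Their median ratio there was 0.925 (quartiles 0.588 and 1.25), and the median SE was 0.205. The loss of Insm1 stays as the biological explanation, a hypothesis here, since Insm1 probes did not check the labels. Only the mutants carried a lacZ allele, so its effects in any cell cannot be told apart from those of the deletion in beta cells. The floxed allele could be deleted in control beta cells as well, so the controls do not stand for intact Insm1.

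The fall of mature beta-cell genes could come from a lower share of beta cells. A lower share would lower such genes alike only if other cells did not express them and their signals were not compressed. Neither condition was tested here. Of the 13 that fell, 8 had a 95% interval that excludes their median fall of −0.56. These 8 ranged from −0.33 for G6pc2, named after its value was seen, to −2.75 for Trpm5. Genes of like brightness also fell unequally. Slc2a2 and Slc30a8, with control means of 13.14 and 13.15, differed by −0.89 and −0.34. The falls of these 13 thus differed in size beyond their errors. Where both conditions hold, this argues against a lower share as their only source. Acinar and alpha-cell markers moved apart (list medians of −1.56 and 0.26), while the endothelial list was not called (−0.07). The 8 members not among the fallers, all but Abcc8 and Ins2 named after their values were seen, went both ways. Entpd3 differed by −0.35 ± 0.13 (called with the replicate block, adjusted p = 0.00345), Slc39a5 by −0.16 ± 0.13 and Adcyap1r1 by −0.06 ± 0.06. Kcnj11 differed by 0.03 ± 0.05, Abcc8 by 0.22 ± 0.06 and Cltrn by 0.23 ± 0.06, with Ins2 and Iapp near the top of the scale. A lower share as a part of the falls stays open, and as the whole of them only if those conditions fail. Acinar tissue is argued against, since the list median was −0.49 with the acinar covariate and −0.39 without. A change of regulation within beta cells stays open as a hypothesis.

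DNA of another strain linked to Insm1 might change signals of neighbouring genes by altering probe binding or regulation. The odds ratio of a call within 20 Mb was 0.752, and the upper end of its interval, 1.10, leaves little room for an excess. Single genes of the window were not tested for this.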

How the results depend on the processing

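The tests with pairs 1 to 3 left out, the immune covariate, the 3′ minus 5′ covariate, the block with covariates or an estimated correlation, and the exact list tests were chosen after the data were seen. Where no cause is given, the cause was not tested. The count of 1594 genes was within 1.5 times under quantile normalisation, median centring, the dim-gene filter, mean probe sets, no trend, array weights and the Y-linked, acinar, immune and 3′ minus 5′ covariates. With every probe set tested, 2740 were called, a count of probe sets and not of genes. The count of genes was 3200 with the replicate block (paired arrays, smaller error) and 828 without pairs 1 to 3 (fewer arrays). It was 421 with block and acinar covariate, 238 with block and 3′ minus 5′ covariate and 9 with block, acinar and immune covariates (larger errors and few residual degrees of freedom). Leaving out 1 array gave 1324 to 1645. The count at 1.5-fold, 434, was 287 without dim genes (fewer genes tested), 214 with block and 3′ minus 5′ covariate and 9 with block, acinar and immune covariates. It was 402 to 449 when 1 array was left out.

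The 11 called lists became 3 with an estimated correlation, 0 with that and the replicate block, and 7 without pairs 1 to 3. They became 6 with block, acinar and immune covariates, 6 by exact permutation over all splits and 6 within pairs. Leaving out 1 array gave 8 to 13. By exact permutation within pairs, acinar markers were called (adjusted p = 0.0299) and islet transcription factors were not (adjusted p = 0.0797), unlike over all splits. The odds ratio near Insm1, 0.752, was 0.293 with block and acinar covariate (Fisher's exact p = 0.021). It ranged from 0.604 to 0.780 when 1 array was left out, with Fisher's exact p under the threshold without mutant replicate 7 (0.662) and control replicates 2 (0.634), 3 (0.640) and 5 (0.604).

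Reversals came with block, acinar and immune covariates for Col6a1 (−0.13), Abcc8 (−0.0361), the mesenchymal list (−0.10) and the cholesterol list (0.14), without pairs 1 to 3 for the immune list (−0.0091), and with block and acinar covariate for the acinar list (0.10, adjusted for itself). With block and 3′ minus 5′ covariate they came for Dcn (−0.0297), Col1a2 (−0.0438), Col6a1 (−0.20), the mesenchymal list (−0.15) and the unfolded protein response list (0.0384), and 42 other named genes lost their call. The 78 called named genes kept their sign under each alternative chosen beforehand in which they were tested, and the dim-gene filter left out 17 of them. 10 of the 78 lost the call when 1 array was left out, 19 without pairs 1 to 3 and 15 with the 3′ minus 5′ covariate. The replicate block ended no call of a named gene and added Rnase1, Mcm7, Msmo1 and Ppy. Among lists it ended the mesenchymal call and added delta-cell and PP-cell, cell cycle and immediate early genes. It changed no other call of these. The change of pseudocount was not run, since values were on a log scale. Signals near the top of the scale limit what Ins2, Iapp and Gcg can show.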

Other observations

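The test below was planned before its result was seen, and the genes it names were chosen after their values were seen.

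Rest was higher in the mutant, and a candidate consequence is a lower signal of genes that its protein represses. A list of 40 neuronal genes, written from general knowledge and sharing 0 genes with the other lists, had 36 measured members. Of these 5 rose and 4 fell, with a median change of 0.01, and camera with an estimated correlation gave p = 0.786. The mean of the list was lower in 3 of 8 pairs (exact permutation p = 0.522). Members moved both ways beyond their errors. The gap junction gene Gjd2 differed by −0.65 ± 0.06 (adjusted p = 3.9e-06) and Gad1, glutamate decarboxylase, by −1.11 ± 0.23 (adjusted p = 0.00453). The neuronal kinase activator gene Cdk5r1 differed by 0.91 ± 0.12 (adjusted p = 8.92e-05). A median at or above 0 had been set beforehand as the result against the hypothesis. It was met only by 0.0062, far within the spread of the members, and after this was seen it was not taken to decide, because members moved both ways. The hypothesis stays open, with no common fall seen.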
